A study of Mus musculus with 4 samples.

How the data were processed

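Spatial transcriptomes of 4 mouse lung sections were analysed, 1 section per group, from a WT mouse given vehicle and KO mice given vehicle or 5 mg/kg rapamycin and labelled 2 h and 8 h. According to the submitters' notes, the authors used Space Ranger 1.3.0 with the mm10 reference, and per the labels the deposited values are counts of UMIs per gene and spot. The label description calls the tissue fresh frozen, while the protocol text names the reagent kit for formalin-fixed tissue. The files hold 19465 genes, without Xist and without mitochondrial genes. Which of the tissue descriptions holds is not given in the sources used here.

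All spots marked as under tissue were kept, which gave 2716, 2174, 2791 and 2276 spots and 41596938, 12104017, 20395951 and 25364464 UMIs in the order above. UMIs of a section were summed per gene and divided by the library total to give CPM. Of the 19465 genes, 19339 were matched to a position in GRCm38.p6. For each pair of libraries the ratio of CPM was given a 95% interval from the exact binomial distribution of the counts conditional on their sum, and single values were given exact Poisson intervals. A gene was counted as at least 2-fold apart when it had at least 10 CPM in either library, a ratio of at least 2 and an interval that excluded 1. A library with 0 counts was set to a floor of 3 counts, which is 0.0721, 0.248, 0.147 and 0.118 CPM in the 4 libraries, and the fold is then a bound. With 1 library per group there is no test, no p-value and no standard error.

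The comparisons were KO vehicle with WT vehicle, each rapamycin section with KO vehicle, and 8 h with 2 h. Each rapamycin section was also set beside the WT section. The KO vehicle library enters 3 of the 4 comparisons. Named genes were fixed by a rule written before the data were examined. They are the 12 highest and 12 lowest ratios among genes past the rule of size whose 4 quadrants do not overlap between sections, without hemoglobin, immunoglobulin and sex-linked genes, together with Psap, Tsc1, Tsc2 and up to 4 members of each list. Genes named outside that rule, such as those near 0 in some sections, were chosen after their values were seen.

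In total 49 gene lists of pathways and cell types were fixed and 37 were described in the comparisons. A member was measured when it had at least 30 UMIs over both libraries, and was called higher or lower at a ratio of at least 1.5 with an interval that excluded 1. Median log2 ratios were set against 10000 random lists drawn from 20 expression bins with the random seed 20240.

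For spot shares, each spot was thinned at random to 2000 UMIs and spots with fewer were left out, at 4, 15, 20 and 9 spots. The threshold was the 95th percentile of the WT section. Moran's I used the 6 nearest array neighbours. Regions came from counts scaled to 10000 per spot, 2000 variable genes, 30 principal components, 15 nearest neighbours and Leiden grouping at a resolution of 0.6. To gauge selection and depth, libraries with the composition of the KO vehicle or WT library were drawn 20 times at the depth of each rapamycin library. These draws hold counting error only.

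The procedure was tested on simulated data with 200 genes moved in each comparison. At 1.5-fold, 0 of 76, 0 of 67, 0 of 66 and 0 of 67 moved genes were called, in the order KO vehicle with WT, 2 h with KO vehicle, 8 h with KO vehicle and 8 h with 2 h. At 3-fold, 55 of 55, 67 of 67, 62 of 62 and 72 of 72 were called, and at 5-fold 69 of 69, 66 of 66, 72 of 72 and 61 of 61. Of 10398, 10209, 10217 and 10233 unmoved genes tested, 0 were called. Genes moved 1.5-fold lie below the minimum ratio of 2, so the rule is not built to call them. The simulated counts hold counting error only and no difference between animals or sections. They check the calculation and give no rate of false calls for these sections. Intervals held the true ratio for 95.3%, 95.01%, 95.1% and 95.1% of genes. On the KO vehicle layout, noise gave a mean Moran's I of -0.00154 with a maximum of 0.0403, and a gradient gave 0.967.

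Alternatives changed 1 choice at a time. They were the scaling by edgeR TMM factors, by DESeq2 median of ratios or by totals without the 50 most abundant genes, the mean over spots, spot filters, thinning, sections without edge spots or without airway, muscle, cartilage and fat spots, parts of the section, minimum CPM, minimum ratio, list membership, percentile and resolution. An alternative with only spots of 5000 to 8000 UMIs and the scalings of the comparisons with WT were added after seeing the data. Images of the sections were not used here. Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.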

Results

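Spatial transcriptomes were recorded from mouse lung on spot arrays, where each array spot captures transcripts from several cells. There were 4 sections, 1 per group. They came from a wild-type (WT) mouse given vehicle, a knockout (KO) mouse given vehicle, and KO mice given rapamycin at 5 mg/kg and labelled 2 h and 8 h. Rapamycin inhibits the growth-controlling kinase complex mTORC1. What the hours are counted from is not given in the sources used here. The series title concerns prosaposin in pulmonary sarcoidosis, a disease of granulomas in the lung.

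The WT section had 2716 spots under tissue and 41596938 UMIs (unique molecules counted). The KO vehicle section had 2174 spots and 12104017 UMIs, the 2 h section 2791 spots and 20395951 UMIs, and the 8 h section 2276 spots and 25364464 UMIs. Median UMIs per spot were 14996 in the WT section, 5401 in the KO vehicle section, 7155 in the 2 h section and 10959 in the 8 h section. The floor of 3 counts, used where a library has 0, is 0.0721 CPM (counts scaled to a common library total) in the WT library, 0.248 in the KO vehicle library, 0.147 in the 2 h library and 0.118 in the 8 h library. With n = 1 section per group no difference here has a replicate check. Ranges after a ratio are 95% intervals that cover counting error only.

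The labels do not name the deleted gene. Tsc1 and Tsc2, the brakes on mTORC1, were both detected in every library, and a transcript measured outside a deleted part would not show a deletion. Tsc1 was at 21.5 CPM in the WT library, 19.99 in KO vehicle, 17.2 at 2 h and 15.3 at 8 h, and its ratio of KO vehicle to WT was 0.928 (0.802 to 1.07). Tsc2 was at 73.7, 58.7, 70.4 and 75.2 CPM in the same order, with a ratio of KO vehicle to WT of 0.796 (0.733 to 0.864). Of 18 measured genes on the list of mTORC1 components and regulators, 2 were higher and 2 lower in KO vehicle than in WT by at least 1.5-fold. Among them were Sesn2 at 1.74-fold and Rictor 2.89-fold lower. Rictor is on that list but is a subunit of the related complex mTORC2. The median log2 ratio of the list lay between -0.13 and 0.01 in the 4 comparisons.

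Psap (ENSMUSG00000004207, chromosome 10, 60277628 to 60302600 in GRCm38.p6) encodes prosaposin, the precursor of the lysosomal saposins that help degrade sphingolipids. It was at 1225 CPM in the WT library, 5573 in KO vehicle, 2248 at 2 h and 1249 at 8 h. The KO vehicle library held 4.55-fold more Psap than the WT library (4.499 to 4.604). The 2 h library held 2.48-fold less than the KO vehicle library (2.45 to 2.51) and the 8 h library 4.46-fold less (4.40 to 4.52). Between the rapamycin sections, Psap was 1.80-fold lower at 8 h (1.77 to 1.83). When each section was divided into 4 quadrants, Psap ranged from 1126 to 1353 CPM within the WT section, 5539 to 5680 within KO vehicle, 2053 to 2498 at 2 h and 1206 to 1281 at 8 h.

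**Figure D1:**
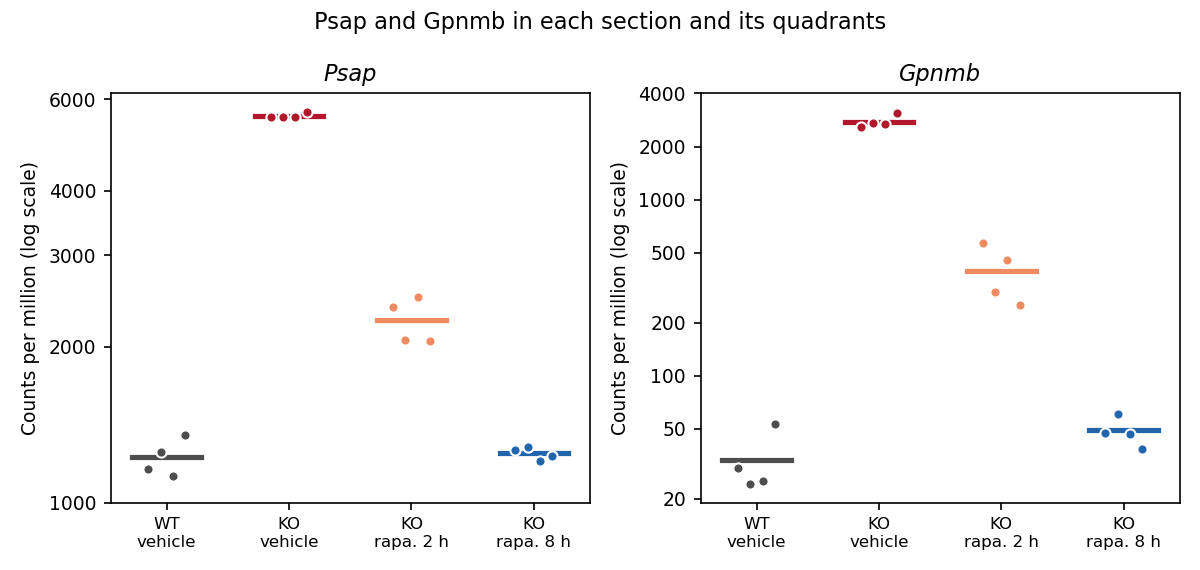
Psap and Gpnmb in CPM on a log axis for the WT vehicle, KO vehicle, rapamycin 2 h and rapamycin 8 h sections, with a line for the whole section and 1 point for each of its 4 quadrants. Psap is at 1225, 5573, 2248 and 1249 CPM and Gpnmb at 33.2, 2753, 393 and 48.8 CPM in that order.

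The KO vehicle section was compared with the WT vehicle section, from which it differs in genotype and in Y-linked transcripts. Most listed transcripts of lysosomes and of granuloma macrophages were higher in the KO vehicle library. Gpnmb, a membrane glycoprotein of lipid-laden and granuloma macrophages, was at 2753 CPM against 33.2 CPM in WT, a ratio of 82.9 (78.5 to 87.5). Ms4a7, a tissue macrophage gene, was 28.4-fold higher (23.7 to 34.3), and the lysosomal protease gene Ctsb 7.72-fold (7.62 to 7.83). Most genes of club, ciliated and alveolar epithelium were lower, with the airway secretory gene Bpifa1 32.8-fold lower (30.2 to 35.7). A region with Bpifa1, Bpifb1 and Calml3 among its leading genes held 6.26% of WT spots and 0 of the KO vehicle spots. Most regions follow the library, so these shares cannot show whether the sections hold different airways. Whether the size of these 3 differences depends on which airways each section holds was not tested. In all, 504 genes were at least 2-fold higher and 675 at least 2-fold lower in the KO vehicle library, of 10875 with at least 10 CPM in either library, and for 496 and 392 of them quadrants did not overlap between the sections.

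The granuloma macrophage list had 15 of 23 measured members higher in KO vehicle, 1 lower and 7 neither. Besides Gpnmb, Trem2 was 7.66-fold, Fabp5 6.81-fold and Cd68 6.03-fold higher. Lysosomal hydrolases and their helpers, a list that includes Psap, had 19 of 32 members higher and 1 lower, among them the cathepsins Ctsd at 6.25-fold and Ctsl at 5.78-fold and the proton pump subunit Atp6v0d2 at 5.12-fold. Median log2 ratios of these lists were 0.99 and 0.94. Both exceeded all 10000 random lists of equally expressed genes, which describes these libraries only. Complement genes had 10 of 13 members higher and none lower, led by C1qb at 13.2-fold, C1qc at 12.5-fold and the receptor C3ar1 at 11.03-fold. Interstitial macrophage and monocyte markers had 11 of 19 higher and 3 lower, with the platelet and macrophage chemokine Pf4 8.60-fold higher.

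Cytokine and chemokine genes had 20 of 23 members higher, 1 lower and a median log2 ratio of 1.73. Ccl3 was 19.0-fold, Tnf 12.7-fold and Ccl2 10.8-fold higher, the last from 21 UMIs in WT and 66 in KO vehicle. Gdf15, a stress-induced cytokine, was 47.4-fold higher (38.2 to 59.4). Heat shock genes had 9 of 11 members higher, with the chaperones Hspa1b at 6.91-fold and Hspb1 at 4.05-fold. Targets of the amino acid stress factor ATF4 had 12 of 20 higher and 2 lower, with the cystine transporter Slc7a11 7.41-fold higher. The glycolysis list had 5 of 13 higher, including Pfkl at 2.26-fold and Hk2 at 1.91-fold, and the cell cycle list 16 of 21, including Mki67 at 3.42-fold. Interferon lists were higher in part, with 9 of 22 interferon gamma genes higher and 2 lower and 7 of 14 type I interferon genes higher and 1 lower, Cxcl9 at 31.5-fold and Rsad2 at 10.8-fold. T cell genes had 12 of 22 higher and 3 lower, with Cd4 20.04-fold and Ctla4 2.98-fold higher. Cd4 does not stand for its list, since in both rapamycin sections below it was lower than in KO vehicle while most T cell genes were higher. B cell genes had 2 of 16 higher and 8 lower, with Fcer2a 6.73-fold lower.

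Several of the largest ratios belonged to granule and red cell genes, and 10 of 14 neutrophil genes were higher and none lower. Cd5l, a secreted macrophage protein, went from 7 UMIs in WT to 2510 in KO vehicle, a ratio of 1232 (597 to 3068). The neutrophil granule genes Camp and Ngp were 1103-fold (616 to 2213) and 173-fold (152 to 199) higher, and Ctsg and Elane 126-fold and 92.2-fold. Mcpt8, a basophil protease, was 143-fold higher. The red cell membrane gene Slc4a1, with 3 UMIs in WT, was 237-fold higher (80.0 to 1159). Hemoglobin transcripts took 1.60% of UMIs in KO vehicle and 0.212% in WT. Pdhb, a subunit of pyruvate dehydrogenase, and Tspan10 had 0 UMIs in WT. Against a floor of 3 counts per library they were 504-fold and 394-fold higher in KO vehicle, with intervals that begin at 408 and 319. Pdhb was at 36.4 CPM in KO vehicle, 67.3 at 2 h and 68.8 at 8 h. Whether its 0 in WT is a difference in expression or a transcript missed in that section was not tested.

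Most genes of airway and alveolar epithelium and of fibroblasts were lower in KO vehicle. The ciliated list had 19 of 21 members lower and 1 higher, with the axonemal motor gene Dnah5 4.495-fold lower. Of 20 club and secretory genes 16 were lower, among them Bpifb1 at 18.5-fold and Retnla at 9.55-fold (9.13 to 9.99). Alveolar type 1 and type 2 lists had 13 of 19 and 13 of 20 members lower and none higher, with Akap5 2.57-fold and the mucin gene Muc1 3.03-fold lower. Fibroblast markers had 18 of 27 lower, capillary and vessel endothelium 11 of 29 lower and 2 higher. Single genes far lower included Nppa, an atrial heart peptide (57.9-fold, 40.9 to 84.7), 1110032A03Rik (72.1-fold, 34.9 to 180), Calml3 (28.6-fold, with 3.31 to 109 CPM across WT quadrants), the dendritic cell lectins Cd209c and Cd209a (27.8-fold and 10.5-fold), Lrrc17 (11.03-fold), Esm1 of endothelial tip cells (9.24-fold), Slitrk6 (8.09-fold), Ccl17 (7.27-fold), Vtcn1 (6.82-fold) and Dapl1 (6.75-fold). The cardiac muscle list, with 7 of 23 members lower, depends on the part of the section, since its median log2 ratio was -0.29 over all spots and 2.31 over spots above the midline.

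The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d had 903, 372, 1032 and 257 UMIs in the KO vehicle library and 0 in the other 3 libraries, so that comparisons with the KO vehicle section also compare sections that differ in these transcripts. Some clock genes also differed between KO vehicle and WT, with Nr1d1 at 204 against 486 CPM and Cry1 at 34.0 against 15.2. Others lay close, with Per3 at 89.1 against 90.4 CPM. No label gives the hour at which these tissues were collected. The split of genes depended on scaling. With library totals 42.7% of the genes at least 2-fold apart were higher in KO vehicle, and with size factors from the median of ratios 53.5% were, at 601 higher and 523 lower. That scaling moved the median of all tested genes from -0.10 to 0.01 on the log2 scale. Lower genes numbered 394 in spots above the midline and 1076 below it, and 1159 in spots with 5000 to 8000 UMIs.

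The 2 h section was compared with KO vehicle, from which it differs in rapamycin and in Y-linked transcripts. Of the granuloma macrophage genes 11 of 22 and of the lysosomal genes 17 of 32 were lower in the 2 h library, with Gpnmb 6.996-fold (6.83 to 7.17), Ctsl 4.98-fold and Fabp5 3.86-fold lower. Most heat shock and clock output genes were lower, with the clock-controlled transcription factor Dbp 6.37-fold lower, and most interferon, B cell and plasma cell genes were higher. There were 268 genes at least 2-fold higher and 307 at least 2-fold lower of 10653 tested.

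In the 2 h library 17 of 32 lysosomal genes were lower than in KO vehicle and 1 was higher, with a median log2 ratio of -0.78. The granuloma macrophage list had 11 of 22 lower and 2 higher, with Atp6v0d2 3.46-fold lower and Ocstamp, a gene of cell fusion with 10 and 56 UMIs, 3.32-fold higher. Heat shock genes were lower in 10 of 11 cases, among them Hspa1b 16.0-fold (14.2 to 18.1), Hspa1a 11.6-fold and Hspb1 9.39-fold. Of 23 cytokine genes 13 were lower and 4 higher, with Ccl2 13.9-fold, Cxcl1 8.85-fold and Il1a 8.06-fold lower. ATF4 targets had 12 of 20 lower and 2 higher, and Gdf15 was 22.2-fold lower (18.0 to 27.7). Complement genes had 5 of 13 lower and none higher, and glycolysis genes 4 of 12 lower and none higher, with Pfkl 2.55-fold lower. Elane was 11.3-fold, Bex1 7.29-fold and Awat1, a wax ester synthase of skin glands, 11.7-fold lower. Psca, with 1 UMI at 2 h and 224 in KO vehicle, was 377-fold lower with a wide interval (67.1 to 14974), and Hmga1b, with 3 UMIs at 2 h, 130-fold lower (43.9 to 634).

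Immunoglobulin transcripts were higher at 2 h, with 25 genes summing to 23921 CPM against 4709 in KO vehicle and 3753 in WT. Jchain, which joins secreted antibody chains, was 7.59-fold higher (7.27 to 7.93) and the B cell coactivator Pou2af1 5.997-fold. The plasma cell list had 10 of 14 and the B cell list 11 of 16 members higher and none lower, with Cd79b 3.22-fold and Cd79a 2.89-fold higher. Interferon gamma and class II genes had 16 of 23 higher, with Iigp1 at 3.27-fold and Gbp4 at 2.76-fold, and type I interferon genes 10 of 14, with Ifi44 at 3.09-fold and Usp18 at 2.89-fold. Neither interferon list had a lower member. T cell genes had 12 of 22 higher, with Icos 2.59-fold higher, and 1 lower, which was Cd4 at 3.34-fold. Other genes far higher were 1110032A03Rik (82.7-fold, 40.0 to 206), the eosinophil chemokine Ccl24 (29.1-fold, 17.2 to 53.5), Nxpe4 (16.4-fold), the incretin receptor Glp1r (10.6-fold), Spg11 (7.23-fold), Frg1 (6.28-fold), Trim5 (6.27-fold), F830016B08Rik (5.96-fold) and Disp2 (5.77-fold).

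Clock genes with a peak near the light to dark transition had 8 of 9 members lower at 2 h, with a median log2 ratio of -1.52, and Per2 and Per3 4.76-fold and 3.91-fold lower. Of the 5 genes of the opposite phase, Npas2 was 9.25-fold (6.27 to 14.2) and Arntl 5.30-fold higher, and Cry1 2.77-fold lower. Ciliated genes had 13 of 21 members higher and 1 lower, and endothelial genes 9 of 29 higher and 2 lower. All 23 genes of the cardiac muscle list were lower, with Mb, myoglobin, 7.08-fold and Tcap 4.82-fold lower. A region with the muscle genes Tcap, Myl3 and Casq2 among its leading genes held 7.73% of KO vehicle spots. It held 0 of the 2 h and 0 of the 8 h spots. Most regions follow the library, and whether the sections hold different pieces of muscle was not tested.

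The 8 h section was compared with KO vehicle in the same way, and it too differs from it in rapamycin and in Y-linked transcripts. Gpnmb was 56.4-fold lower (53.2 to 59.7) in the 8 h library and Gdf15 43.3-fold lower (33.4 to 57.1). Most complement and proliferation genes and 19 of 32 lysosomal genes were lower, while most B cell and T cell genes and 15 of 29 endothelial genes were higher. There were 360 genes at least 2-fold higher and 486 at least 2-fold lower of 10677 tested.

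At 8 h, 19 of 32 lysosomal genes were lower than in KO vehicle and 1 higher, with Atp6v0d2 8.11-fold, Ctsb 6.40-fold and Ctsk 6.15-fold lower and a median log2 ratio of -0.81. The granuloma macrophage list had 13 of 22 lower and 1 higher, with Fabp5 7.23-fold and Cd68 6.55-fold lower. Complement genes had 10 of 13 lower, led by C1qb at 6.71-fold, and macrophage and monocyte markers 12 of 19 lower and 1 higher, led by Ms4a7 at 7.75-fold. Of 23 cytokine genes 15 were lower and 4 higher, with Il6, at 6 UMIs against 99, 34.6-fold lower. Heat shock genes had 9 of 11 lower, and ATF4 targets 13 of 20 lower and 1 higher, with Ddit4, an inhibitor of mTORC1, 3.42-fold lower. Cell cycle genes had 13 of 21 lower and none higher, with Top2a 3.23-fold lower. Genes of the glucocorticoid response had 12 of 17 lower and none higher, with the kinase gene Pdk4 11.3-fold and the metallothionein gene Mt2 10.0-fold lower. Mast cell and basophil genes had 10 of 12 lower, with Fcer1a 10.2-fold lower. Cardiac muscle genes were again lower in 23 of 23 cases, with the same limit from the muscle that each section holds.

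The largest ratios among lower genes at 8 h were Tspan10 (180-fold, 69.8 to 665), Awat1 with 3 UMIs at 8 h (170-fold, 57.4 to 829), Psca with 4 UMIs (117-fold, 45.2 to 434) and Hmga1b (69.2-fold). Stra6l was 26.0-fold, Bex1 23.0-fold, the gluconeogenic gene Pck1 22.9-fold, Ly6k 19.4-fold, the acute phase gene Orm1 18.0-fold and Elane 16.9-fold lower. The B cell list had 15 of 16 members higher and none lower, with Fcer2a 11.8-fold, from 7 UMIs in KO vehicle, Ighd 5.18-fold and Ms4a1 5.08-fold higher. T cell genes had 17 of 22 higher, with Cd8b1 5.27-fold, Cd8a 4.24-fold and Tcf7 3.65-fold higher, and 1 lower, again Cd4, at 6.91-fold. Endothelial genes had 15 of 29 higher and 2 lower, with Tmem100 2.78-fold and the receptor Tek 2.42-fold higher and the adhesion molecule Vcam1 3.97-fold lower. Alveolar type 1 genes had 12 of 19 and ciliated genes 11 of 21 higher, with 0 and 1 lower. Ankrd63, with 1 UMI in KO vehicle and 802 at 8 h, was 383-fold higher (68.5 to 15135). 1110032A03Rik was 72.1-fold, Glp1r 18.9-fold (15.5 to 23.2), Nxpe4 15.3-fold, Ccl24 8.73-fold, Spg11 7.71-fold, Nsg2 6.70-fold, Frg1 6.59-fold, Arhgap20 6.54-fold, Scube1 6.48-fold, H2-Oa 6.07-fold and Trim5 6.04-fold higher. Clock genes with a peak near the light to dark transition had 5 of 9 members higher and none lower, with Dbp 2.51-fold higher.

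**Figure D2:**
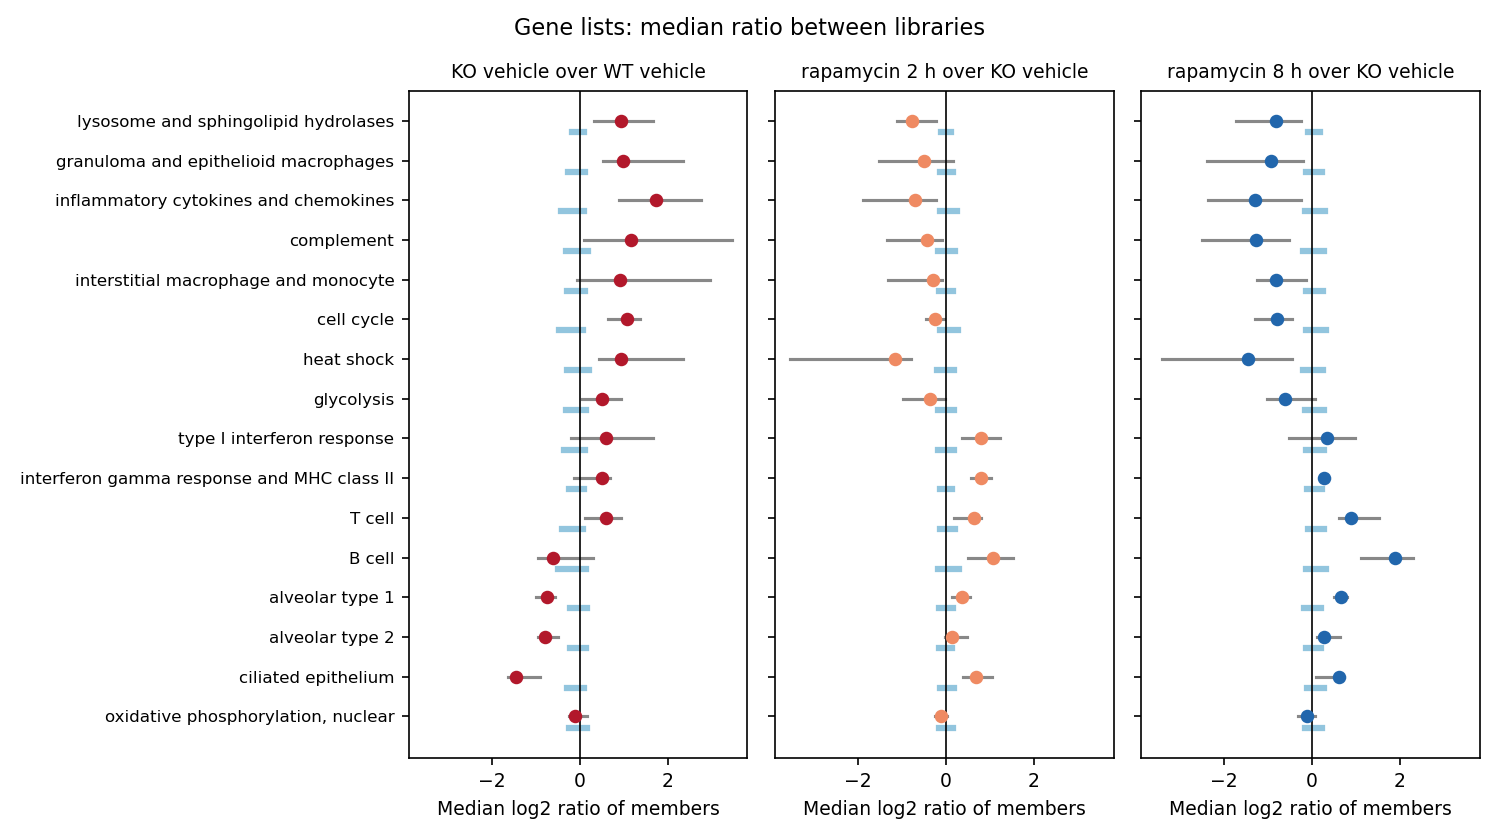
Median log2 ratio of the members of 16 gene lists in 3 comparisons of KO vehicle with WT and of each rapamycin section with KO vehicle. Dots are medians, grey lines their 95% intervals over members, and blue bars the 5th to 95th percentile of random lists of equally expressed genes, with lysosomal genes at 0.94, -0.78 and -0.81.

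The 8 h section was also compared with the 2 h section. Clock and glucocorticoid genes set them apart. Dbp was 16.0-fold higher at 8 h (14.4 to 17.7), Hlf 6.39-fold, Per3 5.35-fold, Per2 5.34-fold and Bhlhe41 4.54-fold. Pdk4 was 10.2-fold (8.63 to 12.1), the glucocorticoid-induced chaperone gene Fkbp5 6.91-fold and the lipase inhibitor gene Angptl4 6.66-fold lower. Genes at least 2-fold apart were fewer than against KO vehicle, at 103 higher and 194 lower of 10608 tested.

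Clock genes with a peak near the light to dark transition had 8 of 9 members higher at 8 h, with a median log2 ratio of 2.18 (1.32 to 2.68 over members). Npas2 was 10.9-fold and Arntl 6.83-fold lower, and Cry1 2.59-fold higher. The glucocorticoid list had 12 of 17 members lower and none higher, with the cell cycle inhibitor gene Cdkn1a 5.33-fold lower. Gpnmb was 8.05-fold lower (7.59 to 8.56), and 14 of 22 granuloma macrophage genes and 8 of 32 lysosomal genes were lower and none higher. Neutrophil genes had 9 of 14 lower, with Ngp 3.89-fold and Camp 3.67-fold lower, and complement genes 9 of 13, with C4b 3.09-fold lower. Interferon gamma and type I interferon lists had 8 of 23 and 7 of 14 lower, with Cxcl9 4.39-fold and Oas2 2.49-fold lower. Cma1, a mast cell chymase, was 24.5-fold lower (15.3 to 41.8), Fam107a 7.50-fold, Myrip 7.26-fold, H2-M2 6.90-fold, Doc2b 6.38-fold and Spon2 5.996-fold. Extracellular matrix genes had 10 of 25 lower and none higher, with elastin, Eln, 4.33-fold lower. B cell genes had 12 of 16 higher and 1 lower, which was Ighm at 3.09-fold. Sox11 was 5.48-fold, Tmem200b 4.49-fold, Lrtm2 4.16-fold, Hic1 4.03-fold, Nkain1 3.74-fold, Cys1 3.47-fold and Tspan4 3.44-fold higher. In spots with 5000 to 8000 UMIs the number of higher genes was 175, and lower genes numbered 298 left of the midline.

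**Figure D3:**
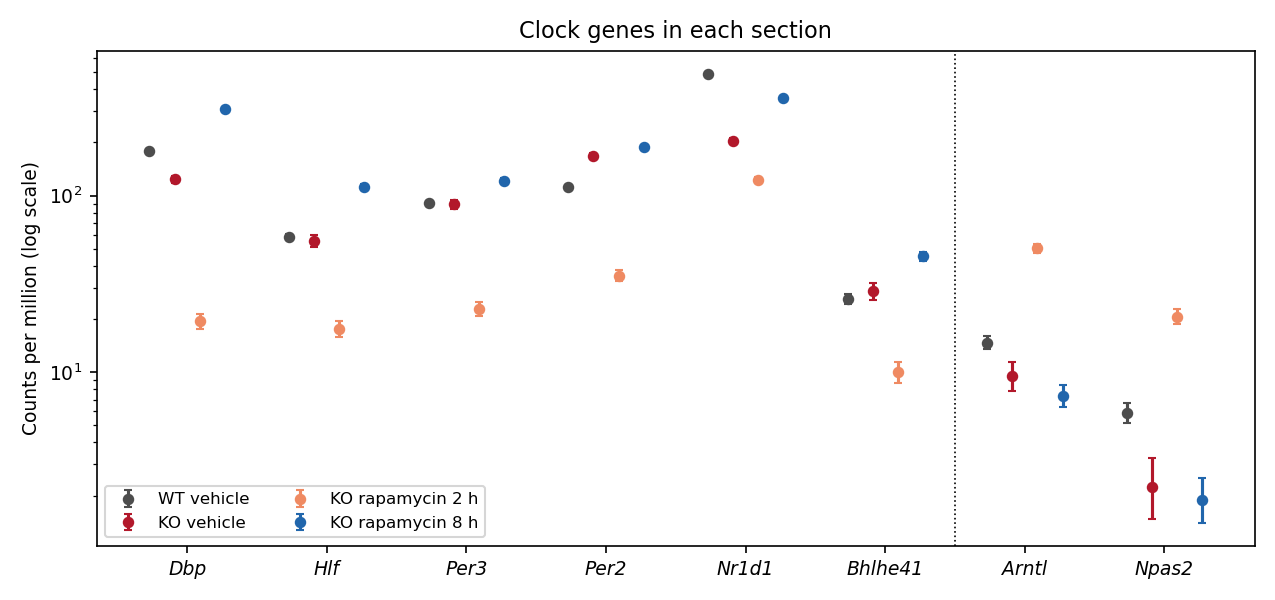
CPM on a log axis of 8 clock genes in the WT vehicle, KO vehicle, rapamycin 2 h and rapamycin 8 h sections, with exact Poisson 95% intervals and a dotted line that sets Arntl and Npas2 apart. Dbp is at 19.4 CPM at 2 h and 309 at 8 h, and Arntl at 50.4 and 7.37.

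Each rapamycin section was also set beside the WT section. Of the 504 genes higher in KO vehicle, 167 (33.1%) were still at least 2-fold above WT at 2 h and 87 (17.3%) at 8 h. Their median log2 ratio to WT was 1.504 in KO vehicle, 0.86 at 2 h and 0.39 at 8 h, and 184 (36.5%) at 2 h and 296 (58.7%) at 8 h were at least 2-fold below KO vehicle. In 20 simulated draws of libraries with the KO vehicle composition at the depth of the rapamycin libraries, 93.5% and 94.1% stayed above. The draws hold counting error only and no difference between animals. Genes picked as far apart in the KO vehicle library can lie closer to WT in another KO lung without rapamycin. The simulated shares are therefore no expectation for an untreated KO section. Of the 675 lower genes, 115 (17.0%) were still at least 2-fold below WT at 2 h and 195 (28.9%) at 8 h, against 88.1% and 88.2% in the simulation. Their median log2 ratio to WT was -1.30 in KO vehicle, -0.63 at 2 h and -0.79 at 8 h, and 136 (20.1%) at 2 h and 143 (21.2%) at 8 h were at least 2-fold above KO vehicle. In libraries simulated with the WT composition, 95.5% and 95.6% of higher genes and 93.01% and 92.98% of lower genes were that far from KO vehicle. Psap was 1.84-fold above WT at 2 h (1.81 to 1.86) and 1.02-fold at 8 h (1.005 to 1.034), and among spots with 5000 to 8000 UMIs the 8 h ratio was 0.904. Lysosomal genes had 9 of 32 members above WT and none below at 2 h, and none above and 2 below at 8 h. Interferon gamma genes were above WT in 14 of 23 cases in both rapamycin sections, and T cell genes in 18 and 21 of 22. At 2 h 297 genes were at least 2-fold above and 256 below WT, and at 8 h 218 and 384. In spots with 5000 to 8000 UMIs the numbers were 438 and 864 at 2 h, so that the balance turned, and 435 and 900 at 8 h. Quadrants did not overlap between sections for 296 of the higher and 136 of the lower genes at 2 h, and for 215 and 160 at 8 h.

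Part of the genes far apart from KO vehicle were the same in both rapamycin sections. Of 10500 genes tested in both, 217 were at least 2-fold higher at 2 h and 297 at 8 h, with 112 in common. For lower genes the numbers were 307 and 486, with 246 in common. Independent lists of these sizes would share 6.14 higher and 14.2 lower genes, which is no yardstick for comparisons that share a library. Both comparisons use the same KO vehicle library, so a departure of that library from other KO lungs would enter each of them and add to the genes in common.

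Spots were compared after each was thinned to 2000 UMIs, which left out 4 WT, 15 KO vehicle, 20 rapamycin 2 h and 9 rapamycin 8 h spots. A spot holds several cells, so these are shares of spots and not of cells. Gpnmb exceeded the 95th percentile of WT spots in 91.3% of KO vehicle spots (90.02 to 92.4, exact binomial), 15.3% of 2 h spots and 1.06% of 8 h spots. Psap exceeded it in 82.7%, 17.9% and 3.04% of spots, and without thinning in 98.3%, 54.1% and 6.81%. The granuloma macrophage list exceeded it in 84.4%, 19.6% and 6.66% of spots, and without thinning in 96.9%, 47.8% and 10.9%. In the WT section the share above that level was 1.99% for Psap and 4.39% for the list. For Gpnmb the 1.06% at 8 h does not mean a level below WT, since Gpnmb was at 48.8 CPM at 8 h against 33.2 in WT. Neutrophil genes exceeded the WT level in 48.3% of KO vehicle, 65.1% of 2 h and 16.9% of 8 h spots, and B cell genes in 4.96%, 53.8% and 18.6%. These shares sum UMIs over a list, and Ighm, at 4391 of 4714 CPM of the B cell list at 2 h and 1419.6 of 1941 at 8 h, carries the B cell share, while 12 of 16 members were higher at 8 h than at 2 h. Erythroid genes did so in 83.7%, 64.2% and 66.3% of spots.

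**Figure D4:**
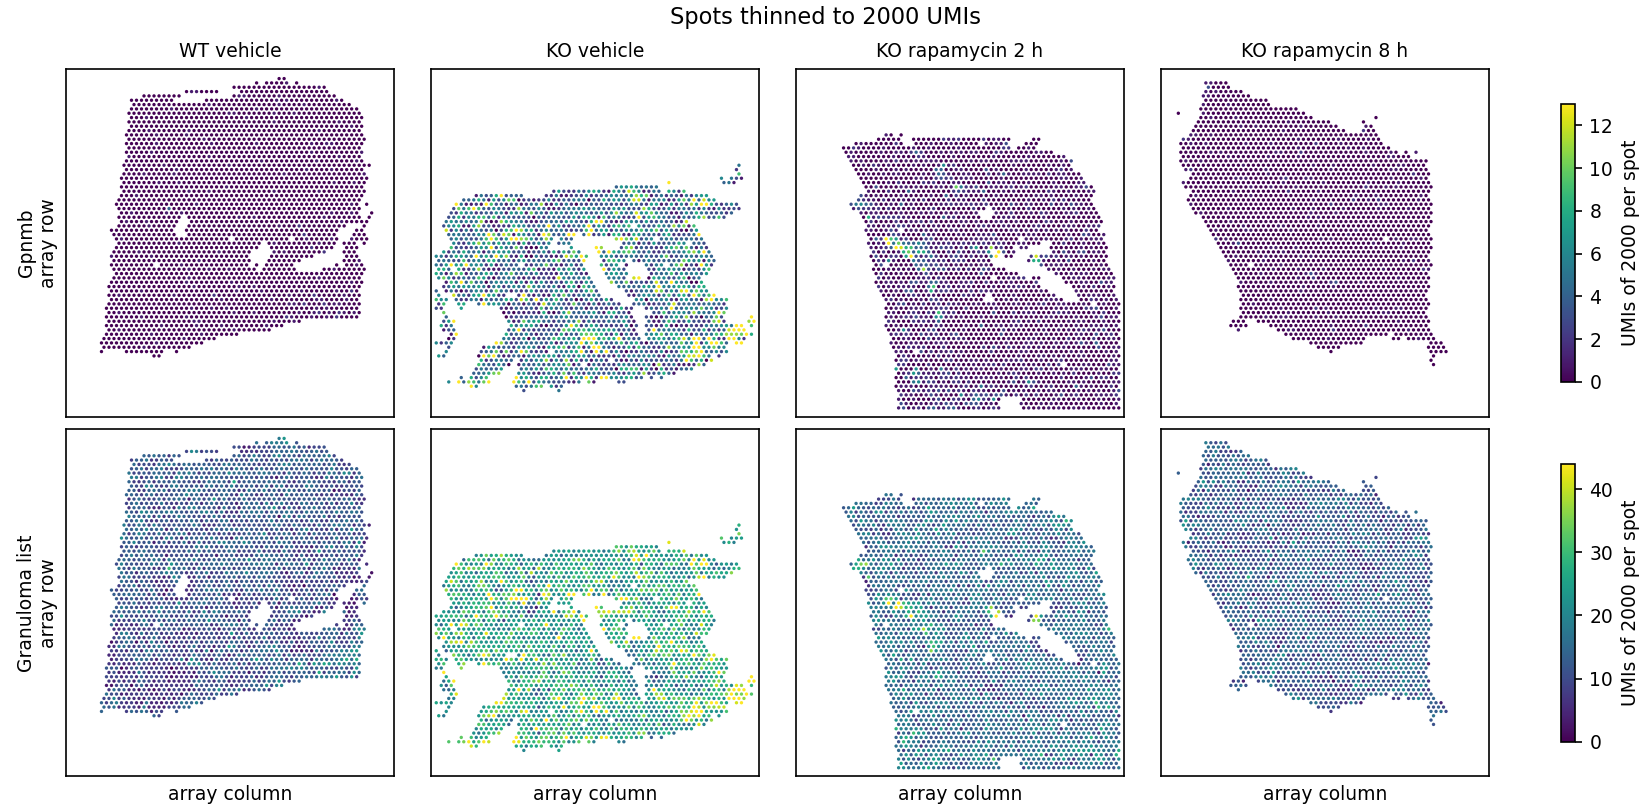
Maps of the 4 sections on a common array scale, each spot coloured by its UMIs of Gpnmb or of the granuloma macrophage list among 2000 UMIs drawn, with colours capped at the 99th percentile of all spots. Spots above the WT 95th percentile for Gpnmb make up 91.3% of the KO vehicle, 15.3% of the rapamycin 2 h and 1.06% of the rapamycin 8 h section.

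Moran's I, a measure of likeness between neighbouring spots, was 0.0754 for Psap in WT, 0.161 in KO vehicle, 0.218 at 2 h and 0.0313 at 8 h, and for Gpnmb 0.170 in KO vehicle and 0.340 at 2 h. Across spots, the Spearman correlation of Psap with the lysosomal list, taken without Psap, was 0.495 in KO vehicle, where that with the granuloma macrophage list was 0.440, and 0.229 at 2 h. In WT and at 8 h it was 0.0543 and 0.0733, lower than with the interferon gamma list (0.137 and 0.0908). Psap has fewer UMIs per thinned spot in WT and at 8 h, and sampling noise alone lowers both measures there, so their sizes are not compared between sections. Grouping all spots by expression gave 14 regions, most of them from 1 section. A region led by Eif2s3y, Ddx3y, Gdf15 and Gpnmb held 81.6% of KO vehicle spots, one led by Sox11 and Igkv8-27 held 80.9% of 8 h spots, one led by Serpina3f and Gm4951 held 63.9% of 2 h spots, and one led by Esm1 held 59.5% of WT spots, so these regions follow the library. A region led by Igkv12-89, Ighg2c and Jchain held 23.97% of 2 h spots and 2.37% of 8 h spots, and one with the ciliary genes Ubxn10, Dlec1 and Tmem212 among its leading genes held 10.9% and 11.2%.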

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

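The tests on quadrants, on sex-linked transcripts and on the clock genes were chosen only after the results were seen, while the test on UMIs per spot was written before its value was computed.

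Clock genes differed in direction between the rapamycin sections. Against KO vehicle, the genes with a peak near the light to dark transition had a median log2 ratio of -1.52 at 2 h and 0.66 at 8 h. Dbp had ratios of 0.157 and 2.51, and Hlf 0.317 and 2.03. The difference was not tested, since each time point has 1 section. Myrip, at 2.72 and 0.375, and Ighg2b, at 15.4 and 0.116, also lay on opposite sides of KO vehicle at 2 h and 8 h, again not tested.

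Hours of rapamycin and the hour of the day at which tissue was collected were weighed for the clock genes. A change in the hour of collection predicts that genes of the opposite phase lie the other way between the sections. Their median log2 ratio of 8 h to 2 h was -0.84, with an interval over members from -3.45 to 1.37 that includes 0. With so few members this interval is their full range, from Npas2 to Cry1. Arntl, Npas2, Clock and Nfil3 were lower at 8 h, and Cry1 alone, which was higher, makes the interval include 0. The genes with a peak near the light to dark transition had a median of 2.18, which either explanation predicts. The explanations cannot be told apart, because no label gives the hour of collection and the hours of rapamycin may have moved with it.

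Higher Psap, Gpnmb and granuloma macrophage genes in the KO vehicle section than in the WT and rapamycin sections were weighed against depth, a local patch and sex. For Psap against WT, fewer UMIs per spot alone do not account for the difference. Among spots with 5000 to 8000 UMIs Psap was still 4.001-fold higher in KO vehicle than in WT (3.72 to 4.31). This window holds 76 of 2716 WT spots, all below that section's 5th percentile of 8340 UMIs, and 1090 KO vehicle spots. These WT spots may not stand for their section, and the test does not cover Gpnmb, the list or the rapamycin sections. A local patch also does not account for this Psap difference, since the lowest KO vehicle quadrant held 4.09-fold more than the highest WT quadrant. Sex cannot be told apart from treatment for the difference of KO vehicle and 2 h, a Psap ratio of 2.48, because these sections also differ in Y-linked transcripts. Among the 3 sections without Y-linked transcripts sex does not account for Gpnmb being 11.8-fold higher at 2 h than in WT (11.2 to 12.5), while at 8 h Gpnmb was at 48.8 CPM against 33.2 CPM in WT and Psap at 1.02-fold, so the 8 h section leaves sex open for KO vehicle.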

How the results depend on the processing

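The depth-matched alternative with 5000 to 8000 UMIs per spot, and the scalings of the rapamycin libraries against WT, were chosen only after seeing the data. The depth-matched alternative rests on 76 WT, 1090 KO vehicle, 1657 rapamycin 2 h and 192 rapamycin 8 h spots. Medians of the granuloma macrophage list stayed within the main interval over members in all 60 alternative values. Of the alternative medians of the other lists 2711 stayed, 64 moved and 8 reversed. Of the alternative ratios of named genes 6614 stayed, 1656 moved and 24 reversed, 15 of these with an interval that includes 1. A list median counts as reversed, and is listed below, only where its main interval excludes 0. A named gene does so only where its main ratio was called at 1.5-fold or more. In spots with 5000 to 8000 UMIs a count of 0 left the ratio of 7 named genes a bound that shows no direction, which are Ccl2, Ear6 and Ighg1 for KO vehicle with WT, Epx and Nppa for 8 h with KO vehicle, and Il6 and Ido1 for 8 h with 2 h. For values below that moved or reversed, the cause was not tested, apart from stricter or looser minimum CPM and ratio, which change how many genes can pass. The alternative with only spots of the largest region that holds at least 10% of every section was not run, because no region does, and the most widely shared one at resolution 0.6 has a lowest share of 0.0460%. Depth limits the KO vehicle library most, where the floor of 3 counts is 0.248 CPM. No value covers differences between animals.

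With a minimum of 2 CPM, genes higher and lower numbered 772 and 1102 for KO vehicle with WT, 538 and 493 for 2 h with KO vehicle, 613 and 801 for 8 h with KO vehicle and 177 and 386 for 8 h with 2 h. With a minimum of 50 CPM, genes higher and lower numbered 241 and 203 for KO vehicle with WT, 80 and 139 for 2 h with KO vehicle, 133 and 224 for 8 h with KO vehicle and 40 and 92 for 8 h with 2 h. With no minimum, genes higher and lower numbered 924 and 1346 for KO vehicle with WT, 710 and 612 for 2 h with KO vehicle, 741 and 991 for 8 h with KO vehicle and 244 and 601 for 8 h with 2 h. At a ratio of at least 1.5, genes higher and lower numbered 1036 and 1753 for KO vehicle with WT, 975 and 812 for 2 h with KO vehicle, 1276 and 1020 for 8 h with KO vehicle and 476 and 533 for 8 h with 2 h. At a ratio of at least 3, genes higher and lower numbered 228 and 157 for KO vehicle with WT, 71 and 116 for 2 h with KO vehicle, 78 and 211 for 8 h with KO vehicle and 21 and 63 for 8 h with 2 h. Genes lower in KO vehicle than in WT numbered 394 above the midline, 1076 below it and 1159 in spots with 5000 to 8000 UMIs. Genes higher at 8 h than at 2 h numbered 175 in spots with 5000 to 8000 UMIs, and lower ones 298 left of the midline.

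The Psap ratio of KO vehicle to WT was 4.81 with TMM factors, 4.91 with the median of ratios, 4.63 without the 50 most abundant genes, 4.42 as a mean over spots, 4.40 in spots thinned to 2000 UMIs, 4.498 without edge spots, 4.82 left of the midline, 4.31 right of the midline and 4.001 in spots with 5000 to 8000 UMIs. The Psap ratio of 2 h to KO vehicle was 0.393 with TMM factors, 0.393 with the median of ratios, 0.438 left of the midline, 0.369 right of the midline and 0.382 in spots with 5000 to 8000 UMIs. The Psap ratio of 8 h to KO vehicle was 0.216 with TMM factors, 0.215 with the median of ratios, 0.228 as a mean over spots, 0.234 in spots thinned to 2000 UMIs, 0.230 above the midline and 0.217 below the midline. The Psap ratio of 8 h to 2 h was 0.546 with the median of ratios, 0.579 in spots thinned to 2000 UMIs, 0.511 left of the midline, 0.608 right of the midline, 0.573 above the midline, 0.534 below the midline and 0.590 in spots with 5000 to 8000 UMIs. For 2 h to WT it was 1.89 with TMM factors, 1.93 with the median of ratios, 1.89 without the 50 most abundant genes and 1.53 in spots with 5000 to 8000 UMIs. For 8 h to WT it was 1.04 with TMM factors, 1.05 with the median of ratios and 0.904 in spots with 5000 to 8000 UMIs. In spots with 5000 to 8000 UMIs, 864 genes were lower at 2 h than in WT, and at 8 h 435 were higher and 900 lower.

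Named genes whose ratio of KO vehicle to WT lay the other way were Ppargc1a at 1.33, Tpsb2 at 1.14, Lum at 1.44, Scara5 at 2.00, Sln at 4.61, Mb at 3.998 and Mybpc3 at 3.48 above the midline. Named genes whose ratio of 2 h to KO vehicle lay the other way were Ccl17 at 1.07 below the midline, with Cma1 at 0.790 right of the midline. Named genes whose ratio of 8 h to KO vehicle lay the other way were Ighg1 at 0.952 in spots thinned to 2000 UMIs, with Bpifa1 at 1.79 right of the midline. Named genes whose ratio of 8 h to 2 h lay the other way were Ocstamp at 1.51, Ccl17 at 1.17, Tcap at 0.918, Trdn at 0.528 and Myh6 at 0.945 in spots with 5000 to 8000 UMIs, with Bpifa1 at 1.72, Reg3g at 3.75 and Lum at 1.14 right of the midline, with Tcap at 0.971, Sln at 0.873, Trdn at 0.726 and Myh6 at 0.704 below the midline, with Trdn at 0.978 in spots thinned to 2000 UMIs. List medians of KO vehicle to WT that changed sign, on the log2 scale, were smooth muscle above the midline at 0.66 and cardiac muscle above the midline at 2.31. List medians of 8 h to KO vehicle that changed sign, on the log2 scale, were adipocyte right of the midline at 0.35. List medians of 8 h to 2 h that changed sign, on the log2 scale, were ciliated right of the midline at 0.0885, cardiac muscle left of the midline at -0.11, cardiac muscle below the midline at -0.59, cardiac muscle in spots with 5000 to 8000 UMIs at -0.49 and adipocyte right of the midline at 0.64.

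Shares of spots above the WT level for Psap were with spots thinned to 1000 UMIs 73.0% in KO vehicle and 4.45% in 8 h, against the 99th percentile of WT 73.9% in KO vehicle, 10.9% in 2 h and 1.19% in 8 h and without thinning 98.3% in KO vehicle, 54.1% in 2 h and 6.81% in 8 h. For the granuloma macrophage list they were with spots thinned to 1000 UMIs 68.5% in KO vehicle and 14.6% in 2 h, against the 99th percentile of WT 63.9% in KO vehicle, 5.59% in 2 h and 0.7499% in 8 h and without thinning 96.9% in KO vehicle, 47.8% in 2 h and 10.9% in 8 h. Moran's I in spots thinned to 1000 UMIs was 0.0295 in WT, 0.113 in KO vehicle and 0.155 in 2 h for Psap, and 0.0947 in WT, 0.156 in KO vehicle, 0.0987 in 2 h and 0.0470 in 8 h for the granuloma macrophage list. Regions numbered 7 at resolution 0.3.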

Other observations

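Tests of the near-zero genes against genome position were chosen only after the result was seen.

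Dendritic cell genes were lower in the KO vehicle library than in WT in 9 of 14 cases and higher in 1, with a median log2 ratio of -1.27, and against KO vehicle higher in 7 of 14 cases and lower in 3 at 2 h, and higher in 8 and lower in 2 at 8 h. Natural killer cell genes followed with 6 of 12 lower and 3 higher in KO vehicle, and 6 of 12 higher and 2 lower at 8 h. Genes of alternative macrophage activation had 6 of 11 members lower in KO vehicle and 1 higher, with Cd209d 14.7-fold lower from 5 UMIs in KO vehicle and Ccl8 12.4-fold higher. Hypoxia genes had 6 of 14 members higher in KO vehicle and none lower, and 8 of 14 lower and 1 higher at 8 h than in KO vehicle. Genes of the oxidative stress response had 7 of 15 lower and 2 higher at 2 h and 7 of 15 lower and 1 higher at 8 h.

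Sterol synthesis genes had 3 of 20 members lower in KO vehicle and none higher, with Hmgcs1 1.60-fold lower, and 3 of 20 higher at 8 h, with Pmvk 1.63-fold higher than in KO vehicle. Fatty acid synthesis genes had 4 of 11 lower in KO vehicle and none higher. Among alveolar macrophage genes the lipid carrier gene Fabp4 was 3.57-fold higher in KO vehicle than in WT, and 4.56-fold and 16.5-fold lower at 2 h and 8 h than in KO vehicle. Mesothelial genes had 7 of 17 higher in KO vehicle and 2 lower. Adipocyte genes had 8 of 13 lower in KO vehicle and 1 higher, and 10 of 13 lower at 8 h than at 2 h.

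When the 4 levels of each gene were split at their largest gap, of at least 5-fold, 12 genes outside the immunoglobulin, hemoglobin and sex-linked groups lay under 2 CPM below the gap and at 10 CPM or more above it. Trim5, at 0, 1.73, 10.9 and 10.5 CPM, has its largest gap between WT and KO vehicle and is not among them. Cd5l, Camp, Pdhb, Mcpt8 and Gm4951 were near 0 in WT only, 1110032A03Rik in KO vehicle only and Pck1 at 8 h only. Psca was near 0 in both rapamycin sections, Dapl1 and Cd209c in all KO sections, and Elane and Awat1 in all but KO vehicle. Without the 10% of spots richest in airway, muscle, cartilage and fat transcripts, 12 of 12 stayed at least 5-fold apart. Such tissue can remain in the other spots, so its being caught in some sections only is not excluded. Stretches of genome that differ between the animals cannot be told apart from other causes, because 0 pairs of these genes lay close together on a chromosome and random sets also had a median of 0. Whether a level near 0 is a transcript missed in that section, and not a difference in expression, was not tested.

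Genes on opposite sides of KO vehicle at 2 h and 8 h numbered 5 of 10500, and include Serpina3g, 2.17-fold higher at 2 h and 2.01-fold lower at 8 h.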
